A study of Homo sapiens with 6 samples.

How the data were processed

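RNA was measured in HepG2 cells, a human line from a liver tumour, 72 hours after transfection with 30 nM of small interfering RNA. Of the 6 libraries, 3 came from cells given a pool against NREP (siNREP) and 3 from cells given a non-target pool (Scramble). Per the labels' protocols, polyadenylated RNA was made into directional libraries that were read from both ends on a HiSeq instrument.

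The deposited values are raw read counts per gene, 1 column per library. Per the submitters' processing notes, the authors used STAR, featureCounts and the human build GRCh38. Versions, annotation release, strand setting and treatment of reads that map to several places are not given in the sources used here. Because the strand setting is not given, reads of overlapping or antisense genes are treated as inseparable, and values of near-identical paralogs as uncertain. The table had 64485 lines with 64440 distinct gene identifiers; 45 identifiers stood on 2 lines, all with counts of 0, and were kept once. GENCODE release 29 on GRCh38 gave symbols, coordinates and transcript models for 58275 identifiers. The other 6165 held between 0.094% and 0.1022% of the counts of a library and stayed in the fits.

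Library totals ran from 21370028 to 24679685 counts. A count of 0 allows up to 3 counts per library, which is 0.122 to 0.14 CPM (counts scaled to a common library total). Intervals and floors cover counting error only. Replicate libraries of one group differed by more than sampling noise, with a chi-square per degree of freedom of 2.47 to 3.88, so no library counted as a copy of another. The labels number the replicates 1 to 3 in both groups without saying that a number marks a shared culture or day.

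The comparison of siNREP with Scramble used edgeR 4.0.16 in R 4.3.3: TMM scaling (factors 0.964 to 1.04), the default expression filter by group, a quasi-likelihood fit with robust estimation on group alone, and Benjamini-Hochberg adjusted p under 0.05. CPM values in the text are TMM-scaled. Standard errors (SE) of log2 fold changes are the fold change divided by the square root of the F statistic. For genes with few counts in Scramble, 95% intervals of the ratio of summed counts are exact and cover counting error.

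Before the data were examined, 21 gene lists, the tests and the rule for named genes were fixed. The rule took NREP, the 8 largest rises and 8 largest falls, and the members of each list with the smallest p. The large changes had to pass the threshold, have a mean of at least 1 CPM and a symbol, and have every siNREP library on the same side of every Scramble library. Each list gave 2 members, or 3 for cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and the TGF-beta response. Members were counted when past the edgeR threshold, adjusted over all genes and over the list alone. Each list with at least 5 measured members was tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), two-sided, adjusted over the lists. Of the list genes, 78 were below the expression filter and were not tested.

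A scan for 7-base words in annotated 3′ UTRs used Python 3.11.15 with numpy 2.4.6. It related each gene's log2 fold change to the presence of each word, with words picked on odd-numbered chromosomes and tested on the others. Word effects were adjusted for UTR length, UTR GC content and expression. It covered genes with a mean of at least 1 CPM and at least 50 UTR bases, words in at least 50 genes, and fold changes limited to 2 log2 units either way. Counts of genes with the picked words cover all 11810 tested genes with an annotated 3′ UTR of at least 50 bases.

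Alternatives were other scalings (median of ratios, upper quartile, library size alone), other expression filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, a fit without robust estimation, glmTreat against a fold of 1.2, and each library left out in turn. For lists they were an estimated correlation, fry and a prior count of 0.5. The edgeR step was tested on simulated data for siNREP against Scramble with 14291 genes. Few of them were changed: 67 by 1.25-fold, 67 by 1.5-fold and 66 by 2-fold. It recovered 76.1% of genes changed 1.5-fold and 90.9% at 2-fold, and 13 of its 160 calls were false.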

Results

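The series asked which transcripts differ in HepG2 cells when NREP is lowered. NREP encodes a small intracellular protein also called P311. Gene counts were available for 3 siNREP and 3 Scramble libraries, with total counts of 22728762, 24679685 and 21370028 in siNREP replicates 1 to 3 and 22974103, 22674395 and 22084243 in Scramble replicates 1 to 3. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

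NREP was lower in every siNREP library. The gene (ENSG00000134986) lies on chromosome 5 from 111662621 to 111997464, minus strand, in GRCh38. Its counts were 1547, 1599 and 1391 in Scramble and 189, 302 and 196 in siNREP. Mean expression was 69.1 ± 3.63 CPM in Scramble and 9.62 ± 1.98 CPM in siNREP (SD, n = 3 each), which is 7.13-fold lower. The log2 fold change was −2.83 (SE 0.085; edgeR adjusted p = 1.9e-21).

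The response was broad and mostly small. Of 14510 genes tested, 8229 (56.7%) differed between siNREP and Scramble, 4103 higher and 4126 lower, while 6281 did not pass the test (edgeR, adjusted p under 0.05). The median absolute log2 fold change of the genes that differed was 0.43, and 65.3% of them changed by less than 1.5-fold. A change of at least 2-fold was estimated for 1186 genes, 638 higher and 548 lower; among genes with a mean of at least 5 CPM it was 418. The direction split depended on scaling: by library size alone 5222 genes were higher and 3223 lower, so that 61.8% of calls were higher and not 49.9%. The first principal component held 75.8% of the variance and separated the groups.

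The largest rises were in genes with few counts in Scramble; a low count need not mean low expression here, since genes that most cells use are also listed near 0. UNC5B, a netrin receptor (chromosome 10, 71212570 to 71302864), had 3 counts over the Scramble libraries and 619 over the siNREP libraries, and the 95% counting interval of the ratio was 65.2 to 930.4. SIGLEC14 had 1 and 145 counts (interval 23.8 to 5347) and WFIKKN2 had 2 and 222 (interval 28.2 to 855). CSTA, which encodes the protease inhibitor cystatin A, went from 0.288 ± 0.099 to 18.2 ± 1.09 CPM (SD, n = 3 each). GRIP2 had 6 and 243 counts (interval 17.0 to 103.4), the chemokine gene CXCL8 6 and 153 (interval 10.6 to 65.4), and ABLIM3 8 and 180 (interval 10.4 to 49.1). ABCA12 had 11 and 417. Scramble counts of single libraries varied, with 2, 4 and 0 for GRIP2 and 1, 7 and 3 for ABCA12, so the size of these rises is uncertain. Counts of SIGLEC14 are uncertain, since 25.55% of its exon bases overlap another gene and it has a close paralog.

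Among the largest falls was CYP17A1, a steroid hydroxylase gene (chromosome 10, 102830531 to 102837533), which went from 44.5 ± 4.33 to 1.40 ± 0.0992 CPM, 31.7-fold lower (SD, n = 3 each). Another gene overlaps 41.13% of its exon bases. AQP10, a water and glycerol channel gene (chromosome 1, 154321090 to 154325325), fell 30.9-fold from 3.66 ± 1.246 to 0.113 ± 0.0252 CPM. The amino acid transporter gene SLC6A19 fell 11.6-fold, C1orf116 11.02-fold, the secreted protease gene HABP2 10.4-fold, PRR15L 7.86-fold, NAALADL1 7.54-fold and B3GNT3 6.72-fold. The largest edgeR adjusted p among these 16 genes was 1.66e-14, for CXCL8. The annotated 3′ UTRs of AQP10, SLC6A19, C1orf116, HABP2 and B3GNT3, and of UNC5B and GRIP2 among the rises, carry at least 1 copy of the 7-base words GAAGGCT or CCCAAGA, whose carriers were lower as a class.

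**Figure D1:**
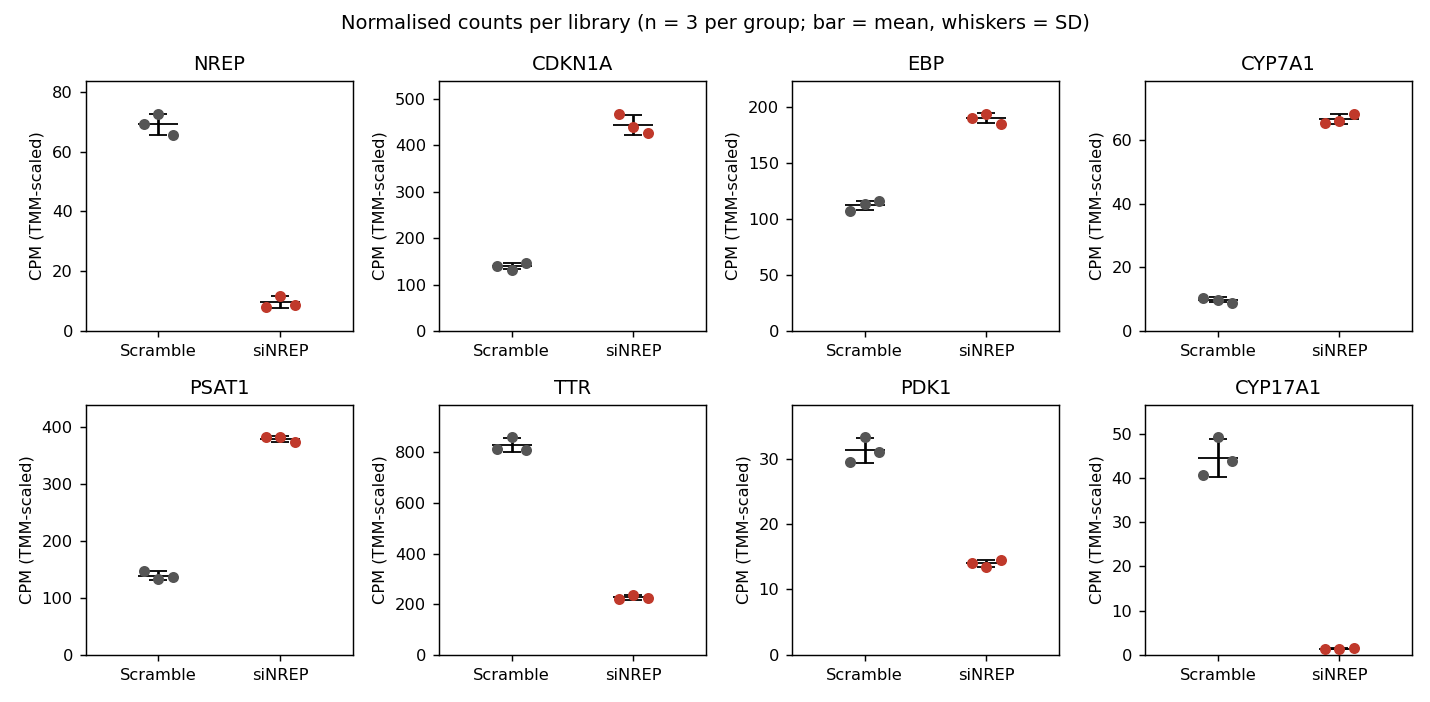
TMM-scaled CPM of 8 named genes in each of the 3 Scramble (grey) and 3 siNREP (red) libraries; points are libraries, bars the mean and whiskers the SD. NREP falls from a mean of 69.1 to 9.62 CPM, and in each panel the siNREP libraries lie on one side of the Scramble libraries.

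Targets of p53 rose together. Of 20 measured, 19 were higher and none lower, with a median log2 fold change of 0.67 (camera adjusted p = 6.25e-09; adjusted p = 0.158 with an estimated correlation). CDKN1A, a cell cycle inhibitor gene, rose from 140 ± 6.98 to 444 ± 21.8 CPM (SD, n = 3 each), and FDXR, a mitochondrial electron carrier gene, had a log2 fold change of 1.32 (SE 0.043).

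Genes of cholesterol synthesis and LDL uptake were higher: 19 of 24 rose and 1 fell, with a median log2 fold change of 0.49 (camera adjusted p = 2.59e-06; adjusted p = 0.369 with an estimated correlation). The sterol isomerase gene EBP rose by 0.76 (SE 0.043), IDI1 by 0.72 (SE 0.043) and SREBF2, which encodes a master transcription factor of the pathway, by 0.67 (SE 0.04) on the log2 scale. SREBF2 carries 1 of the 7-base words. In xenobiotic metabolism 9 of 12 rose and 2 fell (camera adjusted p = 0.0378; adjusted p = 0.369 with an estimated correlation), and the call was lost by library size alone (adjusted p = 0.0557), at a mean of at least 1 CPM (0.0946) and without siNREP replicate 3 (0.0563). UGT1A1, the bilirubin conjugating enzyme gene, had a log2 fold change of 2.01 (SE 0.112), with 49.85% of its exon bases shared with other genes and 1 of the words in its 3′ UTR. GSTA1 had 1.14 (SE 0.073); it has close paralogs.

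Glycolysis and hypoxia genes were lower. In glycolysis and gluconeogenesis 15 of 21 fell and 1 rose, with a median of −0.50 (camera adjusted p = 0.00118; adjusted p = 0.6 with an estimated correlation). The glucose transporter gene SLC2A1 had a log2 fold change of −0.55 and the pyruvate kinase gene PKM −0.53 (SE 0.039 each). In the hypoxia list 13 of 18 fell and 2 rose, with a median of −0.49 (camera adjusted p = 0.00354; adjusted p = 0.839 with an estimated correlation); without members that carry a word the median was −0.33 (camera adjusted p = 0.046). PDK1, an inhibitor of pyruvate dehydrogenase, had −1.16 (SE 0.074) and carries both words. P4HA1, a collagen hydroxylase gene, had −0.84 (SE 0.046).

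Library composition moved with the groups and so with each of these 5 lists. Mitochondrial genes took 11.99% ± 0.104 of counts in siNREP and 9.67% ± 0.243 in Scramble, and the 10 most abundant genes took 15.5% ± 0.199 and 18.5% ± 0.114 (SD, n = 3 each). Of 13 mitochondrially encoded mRNAs 10 were higher and 2 lower (camera adjusted p = 0.0601), with log2 fold changes of 0.89 for MT-ND1 and 0.55 for MT-ND2 (SE 0.039 each); nuclear copies make such counts uncertain. Of 23 markers of other liver cell types, 9 were measured in these HepG2 libraries, of which 6 were lower and none higher (camera adjusted p = 0.0601). LYZ had a log2 fold change of −0.88 (SE 0.039; 33.96% of its exon bases overlapped) and KRT19 −0.82 (SE 0.043).

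**Figure D2:**
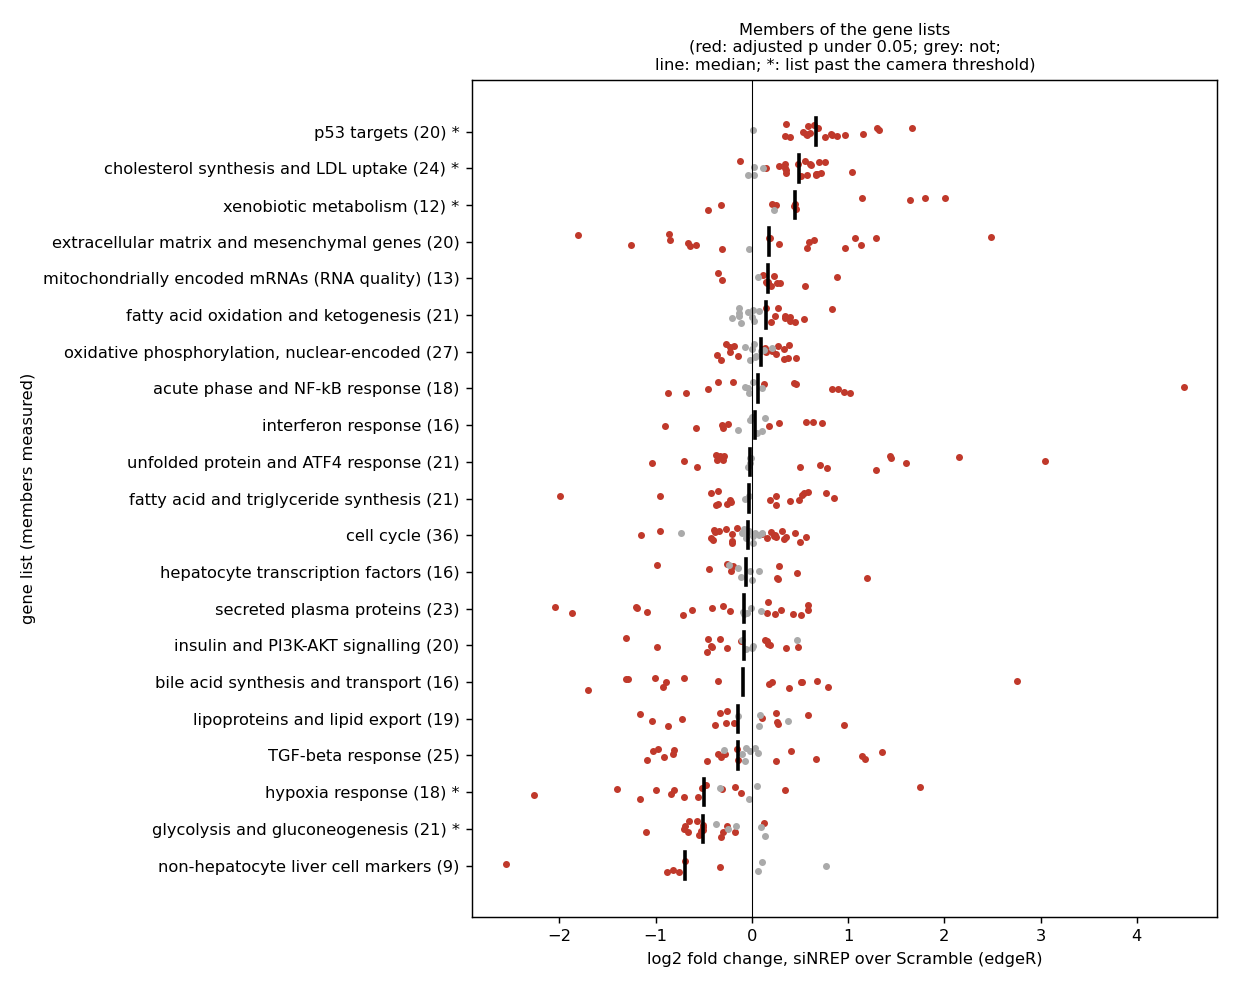
Log2 fold change (siNREP over Scramble, edgeR) of each measured member of the 21 gene lists; red points have an adjusted p under 0.05, grey points do not, black lines are list medians and asterisks mark lists past the camera threshold. The p53 list has a median of 0.67 and the hypoxia list one of −0.49.

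**Figure D3:**
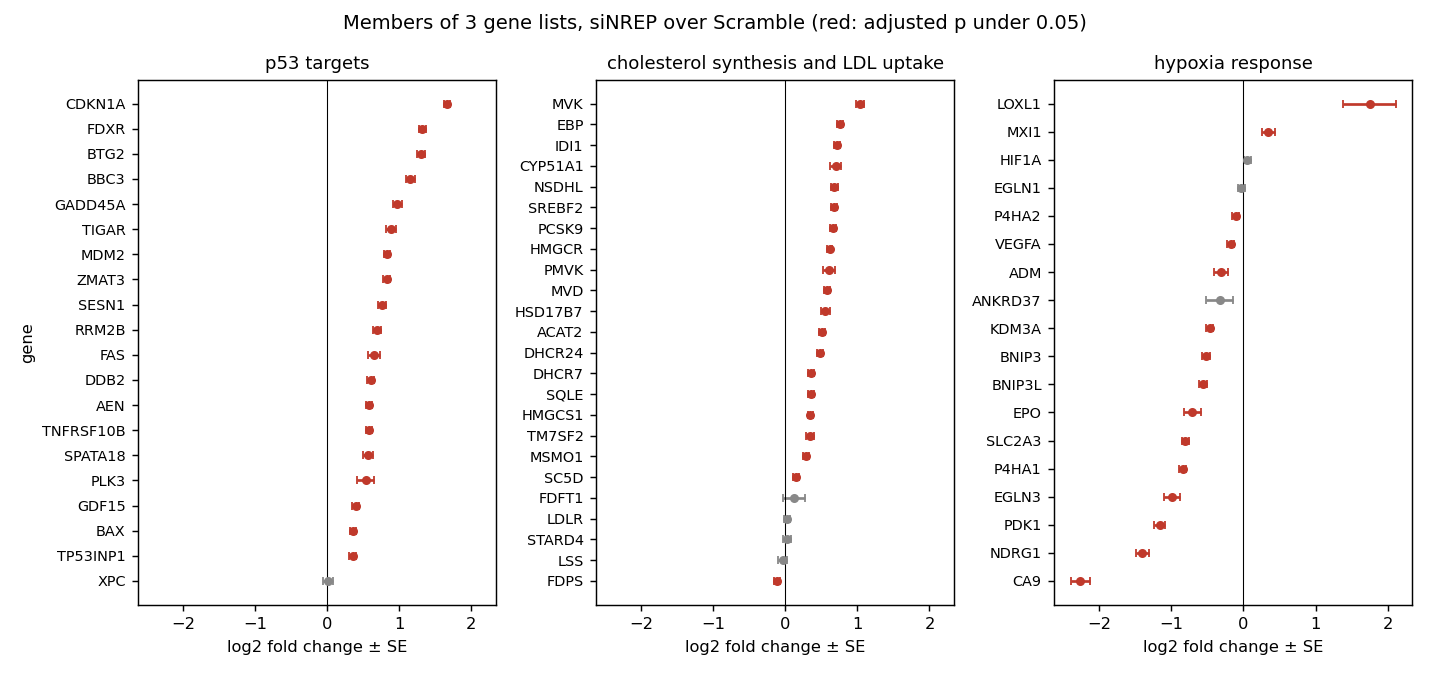
Log2 fold change (siNREP over Scramble) with its standard error for each measured member of 3 lists; red points have an edgeR adjusted p under 0.05. Of the p53 targets 19 of 20 are higher, of the cholesterol genes 19 of 24, and of the hypoxia genes 13 of 18 are lower.

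Other metabolic and liver lists moved without a common direction past the test. Fatty acid oxidation had 11 of 21 higher and none lower (camera adjusted p = 0.0648), including CPT1A, the entry enzyme of mitochondrial oxidation, at 0.83 (SE 0.06), HADHB at 0.54 (SE 0.04) and EHHADH at 0.44 (SE 0.053). Fatty acid and triglyceride synthesis had 10 of 21 higher and 9 lower (camera adjusted p = 0.871), with ELOVL5 at 0.85 (SE 0.044), MLXIPL at 0.77 (SE 0.046) and the lipid droplet gene CIDEC at −0.96 (SE 0.066). Lipoproteins and lipid export had 6 of 19 higher and 9 lower (camera adjusted p = 0.65), with the sterol exporter gene ABCG5 at −1.16 (SE 0.084; 1 of the words) and APOA5 at −0.88 (SE 0.055). All 16 measured bile acid genes passed, 8 in each direction (camera adjusted p = 0.985): CYP7A1, the rate-limiting enzyme of bile acid synthesis, rose 6.76-fold from 9.81 ± 0.791 to 66.4 ± 1.52 CPM (SD, n = 3 each), and AKR1D1 fell 2.47-fold.

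Plasma protein genes were 8 higher and 10 lower of 23 (camera adjusted p = 0.373). The transthyretin gene TTR fell 3.65-fold and the alpha-fetoprotein gene AFP, at 28631 CPM in Scramble, fell 2.29-fold to 12527. Of 16 hepatocyte transcription factors 5 were higher and 5 lower (camera adjusted p = 0.865), with CEBPB at 1.19 (SE 0.079) and NR5A2 at −0.99 (SE 0.083). Nuclear-encoded oxidative phosphorylation had 11 of 27 higher and 7 lower (camera adjusted p = 0.575), with SDHA at 0.38 (SE 0.04) and ATP5F1B at −0.32 (SE 0.037).

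Signalling and stress lists were also divided. In the TGF-beta response 6 of 25 were higher and 12 lower (camera adjusted p = 0.458): ID2 had −0.81 (SE 0.049), CCN1 −0.91 (SE 0.067), and BAMBI, a decoy receptor gene, rose 2.21-fold. Extracellular matrix and mesenchymal genes were 11 higher and 8 lower of 20 (camera adjusted p = 0.804), with SPARC 3.51-fold lower (1 of the words) and ACTA2 2.44-fold higher (30.11% of its exon bases overlapped). Insulin and PI3K-AKT genes were 6 higher and 9 lower of 20 (camera adjusted p = 0.575). PIK3R1 had −0.98 (SE 0.058) and carries 1 of the words, and AKT2 had 0.48 (SE 0.044) and carries both. Cell cycle genes were 12 higher and 12 lower of 36 (camera adjusted p = 0.966), with PCNA at 0.50 (SE 0.041) and MCM5 at 0.56 (SE 0.047). The unfolded protein and ATF4 list had 9 of 21 higher and 8 lower (camera adjusted p = 0.658). Its serine synthesis genes PSAT1 and PHGDH rose 2.72-fold and 2.44-fold. The 9 higher genes were ATF4, ATF3, DDIT3, TRIB3, ASNS, PSAT1, PHGDH, SLC7A11 and VLDLR. The 8 lower genes were HSPA5, HSP90B1, PDIA4, PDIA6, DNAJB9, HERPUD1, SEL1L and XBP1, mostly genes of protein folding in the endoplasmic reticulum. This division was seen in the values and was not tested. Interferon genes were 5 higher and 5 lower of 16 (camera adjusted p = 0.985), with STAT2 at −0.90 (SE 0.058) and OAS1 at 0.73 (SE 0.064). Acute phase and NF-kB genes were 8 higher and 5 lower of 18 (camera adjusted p = 0.658), with FGL1 at 1.02 (SE 0.043) and STAT3 at 0.95 (SE 0.041).

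Adjusted over the list alone, the counts were the same except for 7 higher in lipoproteins, 7 higher in insulin signalling and 2 higher in glycolysis. With an estimated correlation camera called none of the 21 lists, and 2 (p53 targets and cholesterol synthesis) had an unadjusted p under 0.05, while the directional fry test called 15. Signs differed in 6 lists not called by camera: fatty acid synthesis (median −0.03, mean −0.02) and bile acids (median −0.09, mean −0.13) against an upward test, the ATF4 list (median −0.02, mean 0.42, upward), interferon (median 0.03, mean 0.01) against a downward test, extracellular matrix (camera up, fry down) and cell cycle (camera down, fry up).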

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

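The corrections for GC content and length, the removal of mitochondrial genes and the omission of genes with the 7-base words were chosen only after the result was seen; the other settings were planned. All 1102 values of named genes kept their direction and their side of the threshold. That was largely set by their choice from the same fit for large changes or small p, and named genes below a filter gave no value. Calls over all genes moved more: of the 8229, 7326 were shared by library size alone and 8210 with median of ratios. NREP stayed lower under each setting run, with log2 fold changes from −3.02 to −2.72. Counts of changed genes ran from 6726 at a mean of at least 5 CPM, where 9989 genes were tested, to 8451 with the GC and length correction. Leaving out genes with either word or no annotated 3′ UTR of at least 50 bases was a subset of the main calls. Of the 9084 genes kept, 5531 were changed, 2998 higher and 2533 lower, and 632 at least 2-fold. Over all 14510 genes it was 8229, 4103 higher and 4126 lower. Genes left out with 1 word were 931 lower and 633 higher, and those with both 175 and 76. Why carriers fell more often was not tested by this omission. DESeq2 gave 7359 genes and shared 7348 with edgeR.

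The number changed at least 2-fold was 418 at a mean of at least 5 CPM, where fewer genes were tested, and 4282 past glmTreat against a fold of 1.2, which asks for a smaller change. Leaving out each library in turn gave 7599 to 8073 changed genes.

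The replicate number as a block gave 8188 genes, of which 8118 were shared, and 5 called lists, and it changed no call of a named gene or list. Same-numbered libraries did not deviate together (correlations −0.031, 0.009 and 0.01 across genes), so the numbers were not taken to pair them.

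Camera called 5 lists, none with an estimated correlation (a count of 0) and 15 with fry. Camera adjusted p with an estimated correlation was 0.158 for p53 targets, 0.369 for cholesterol synthesis and for xenobiotic metabolism, 0.6 for glycolysis and 0.839 for hypoxia. The estimated correlation for xenobiotic metabolism was 0.006, below the preset 0.01, so a larger correlation does not account for that loss. It was 0.047 for p53 targets, 0.107 for cholesterol synthesis, 0.257 for glycolysis and 0.541 for hypoxia. So the other losses need not come from correlation alone. Xenobiotic metabolism also lost its call by library size alone (adjusted p = 0.0557), at a mean of at least 1 CPM (0.0946) and without members that carry a word (0.0715). Its adjusted p ran from 0.0245 to 0.0563 over the libraries left out, the highest without siNREP replicate 3. Lists not called in the main test kept that side in 238 values and passed the threshold in 17. In a simulation of 14291 genes at this depth, spread and number of libraries, 76.1% of 1.5-fold changes and 53.7% of the smallest changes simulated, below 1.5-fold, were recovered; depth was not varied on its own.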

Other observations

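The splits of the libraries, the held-out rank of the 7-base words, the share of falls without those words or their 6-base cores, the 8 gene lists of this part and those lists without shared members or word carriers were tests chosen only after the result was seen.

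In siNREP libraries, whose share of mitochondrial counts was also higher (11.99% against 9.67% in Scramble), amino acid supply genes rose: 16 of 21 genes of amino acid synthesis and transport were higher and 4 lower (camera adjusted p = 7.4e-05; adjusted p = 0.267 with an estimated correlation). Of its genes 4 (PSAT1, PHGDH, SLC7A11 and ASNS) also stand in the ATF4 list, whose rises had been seen; without them 12 of 17 were higher and 4 lower (camera adjusted p = 0.00595; adjusted p = 0.394 with an estimated correlation). The list includes PSAT1, PHGDH and MTHFD2 (log2 fold change 1.41, SE 0.045) of serine and one-carbon metabolism, and the cystine transporter gene SLC7A11 (2.16, SE 0.07). Of 19 aminoacyl-tRNA synthetase genes 11 were higher and 4 lower (camera adjusted p = 0.0268; adjusted p = 0.267 with an estimated correlation), with SARS1 at 1.09 (SE 0.043) and MARS1 at 0.93 (SE 0.044). NRF2 targets and glutathione genes had 15 of 20 higher and 2 lower (camera adjusted p = 5.74e-05; adjusted p = 0.267 with an estimated correlation), and 12 of 17 higher and 2 lower without the 3 genes shared with earlier lists (camera adjusted p = 0.000739; adjusted p = 0.394 with an estimated correlation). Lysosomal genes had 11 of 22 higher and 3 lower (camera adjusted p = 0.0268; adjusted p = 0.394 with an estimated correlation), with the cathepsin gene CTSD at 1.16 (SE 0.047).

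Cytosolic ribosomal protein genes were lower, and genes of entry into the endoplasmic reticulum were lower with a call that did not hold without carriers of the 7-base words. Of 32 cytosolic ribosomal protein genes 24 were lower and 3 higher (camera adjusted p = 4.11e-05; adjusted p = 0.394 with an estimated correlation), with RPL4 at −1.03 (SE 0.037) and RPL6 at −0.99 (SE 0.038); processed pseudogenes make these counts uncertain. Of 28 translocon and N-glycosylation genes 16 were lower and 3 higher (camera adjusted p = 0.0068; adjusted p = 0.305 with an estimated correlation), led by SSR2 at −2.43 (SE 0.051), SRPRA at −1.64 (SE 0.048) and SRP72 at −0.56 (SE 0.045), each with 1 of the 7-base words in its 3′ UTR. Without the 4 carriers 13 of 24 were lower and 3 higher, the median went from −0.14 to −0.11, and the call was lost (camera adjusted p = 0.0532; adjusted p = 0.4 with an estimated correlation). Complement and coagulation (7 higher and 8 lower of 23; camera adjusted p = 0.544; without genes of earlier lists 4 higher and 7 lower of 17; camera adjusted p = 0.375) and DNA repair (7 higher and 4 lower of 23; camera adjusted p = 0.532) were not called. Library composition moved with the groups and so with each called list of this part. Mitochondrial genes took 11.99% of counts in siNREP and 9.67% in Scramble (means, n = 3 each). Mitochondrial rRNA took 1.76% and 1.21%, and the 10 most abundant genes 15.5% and 18.5% (means, n = 3 each). Of 9 measured markers of other liver cell types 6 were lower in HepG2, a cell line. That list was not called (camera adjusted p = 0.0601). The genes named here were chosen after their values were seen.

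Genes with certain 7-base words in the 3′ UTR were lower in siNREP libraries. On odd-numbered chromosomes GAAGGCT (log2 effect −0.18, SE 0.0206) and CCCAAGA (−0.17, SE 0.0203) ranked lowest of 15872 words, and on the held-out chromosomes they again ranked 1 and 2 of 15734 (−0.17, SE 0.0228 and −0.16, SE 0.0221), as siRNA seed matches of the NREP pool would give; the words lie in 21 and 22 of 23 NREP transcripts, but 37.9% of all words lie in at least 1. Direct seed matches through these 2 words in 3′ UTRs, as the cause of every fall, are argued against by genes without either word. Of those, 27.88% were lower and 33.0% higher, beside 39.42% lower and 26.8% higher with 1 word and 48.08% lower and 20.88% higher with both. Direct matches in members of the hypoxia and glycolysis lists, as the whole cause, are argued against by a pooled median of −0.33 among members without a word. Leaving out carriers moved the hypoxia median from −0.49 to −0.33 (camera adjusted p from 0.00354 to 0.046). That of glycolysis went from −0.50 to −0.41 (camera adjusted p from 0.00118 to 0.00338). Falls downstream of seed matches in other genes are not covered by these values. Seed matches of the Scramble pool would make carriers of a word higher in siNREP. The most positive word had t = 3.79 on odd-numbered chromosomes, against −8.63 for GAAGGCT. On the held-out chromosomes the values were 3.81 and −7.38. In the 224 genes with no 6-base core of a word in any annotated transcript, 20.54% were lower (exact 95% binomial interval 15.4% to 26.4%) and 38.39% higher, a smaller share of falls than without the full words; the next most negative word that does not overlap these had t = −3.77 over all scanned genes, against −11.3 and −10.8 for the 2 words. A word was found in 38.46% of genes lower at least 2-fold and 22.18% of genes higher at least 2-fold (two-sided Fisher's exact test, odds ratio 2.19, p = 1.56e-07, on genes that include those used to pick the words). Unlike the word effects, these shares and those by number of words or by core were not adjusted for UTR length, GC content or expression. A longer UTR has more room for a word, so length may enter these shares. Part of the falls may therefore come from direct pairing of the pool with other transcripts, while loss of NREP, and changes downstream of either, stay open and untested, since the siRNA sequences are not given in the sources used here and 1 pool was used.

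The 5 called lists were weighed against library composition. GC content and gene length bias between libraries is argued against as the whole cause, since all 5 stayed past the threshold after a spline correction that kept 7727 of 8229 calls. A larger share of mitochondrial counts in the siNREP libraries would by itself shift all other genes the same way. As such a shift it is argued against as the whole cause, since the lists moved in opposite directions. Median log2 fold changes were 0.667 for p53 targets, 0.495 for cholesterol synthesis and 0.445 for xenobiotic metabolism. They were −0.504 for glycolysis and −0.495 for hypoxia. Whatever else goes with that share stays open. All 5 lists stayed past the threshold with mitochondrial genes removed. That setting kept 8191 of 8229 calls with a median shift of 0, so it does not decide what stays open. Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave as many genes, 8229 against a highest other of 0 in edgeR (88 to 138 genes at an unadjusted p under 0.05); 10 splits are too few for a share under 0.05.

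Genes that most cells use were listed at or near a count of 0. Of 216 genes in 7 such families, 16 had 10 or fewer counts over the 6 libraries and 12 had 0, PSMC4 and NDUFS1 among them (PSMA8, PSMB8, PSMB9 and PSMB11 are tissue-restricted or inducible members), and VIM was listed at 0. Overlap with another annotated gene is argued against by a median of 0.945% of exon bases overlapped. A candidate explanation is a second copy on an alternate or patch sequence in the reference, whose reads map to both: 81.8% (27 of 33) of commonly used genes of the major histocompatibility region, which has alternate haplotype sequences, had 10 or fewer counts. The reference sequences the authors used are not given in the sources used here, so genes listed at 0 cannot be read as silent.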
